A study of Homo sapiens with 45 samples.

How the data were processed

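Total RNA of human dendritic cells, primary fibroblasts and primary keratinocytes was measured by RNA-seq in 45 libraries, 3 for each of 5 conditions in 3 cell types. Per the labels, cells in 6-well plates received bacteria at a multiplicity of infection of 1 for 24 h, and stranded libraries were read as pairs of 150 bp. The labels do not give the number of isolates per group or the annotation release. For each gene the authors deposited expected counts (expected_counts), the number of read pairs estimated by RSEM from the aligned reads, without normalization. The authors also deposited FPKM (fpkm), the same fragments scaled by RSEM to the effective length of the gene and to the mapped fragments of the library. The authors name cutadapt, STAR 2.5.2b and RSEM 1.3.0 and the build hg38. Of 58381 gene identifiers 56888 match GENCODE release 29 with their version and 58261 without it, and gene names, types and positions were taken from that release. A symbol shared by several identifiers, 1733 in all, was kept as separate genes.

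The 565 genes on the Y chromosome, in the regions it shares with X, or tied to X inactivation were removed to protect donors, leaving 57816. Totals per library ran from 13.97 to 23.76 M expected counts with a median of 18.69 M. Because 12.8% of the values are not whole, they were rounded. At this depth a gene with all 3 libraries of a group at 0 was given a floor of 3 counts per library for an "at least" fold, and a gene with few counts a 95% exact binomial interval.

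Each cell type was fitted by itself with 15 libraries in R 4.3.3 with edgeR 4.0.16: filterByExpr by group, TMM factors, and the quasi-likelihood (QL) F test on 10 residual degrees of freedom, with Benjamini-Hochberg (BH) adjusted p below 0.05 over all measured genes. Prior degrees of freedom were 7.9, 7.3 and 9.7 in keratinocytes, fibroblasts and dendritic cells, and the common biological coefficients of variation 6.6%, 7.2% and 6.3%. The 18 contrasts set each isolate group against diluent, Rm_HV against Rm_AD, and SA_AD against CoNS_HV in each cell type. Whether Rm_HV over Rm_AD differs between cell types was tested as an interaction in the 18 R. mucosa libraries. Log2 fold changes are given with standard errors, and counts scaled to library size (CPM, from edgeR) with standard deviations.

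Gene lists, named-gene rule, contrasts and first alternatives were chosen before the data were examined. The 29 lists hold 564 genes: TNF and NF-kB response, TNF ligand and receptor families, inflammatory cytokines, chemokines, interferon-stimulated genes, type 2 and itch mediators, epidermal differentiation and barrier, epidermal lipid synthesis, antimicrobial peptides and S100 proteins, epithelial-mesenchymal transition, proteases with growth factors and wound keratins, collagens and matrix, cholinergic signalling, pattern recognition receptors, cholesterol synthesis, prostaglandins and eicosanoids, cell cycle, hypoxia and glycolysis, unfolded protein and amino acid stress, oxidative and metal stress, dendritic cell maturation, replication-dependent histones, mitochondrial transcripts as a sign of RNA quality, and markers of keratinocytes, fibroblasts, melanocytes, endothelial cells, lymphocytes, and myeloid and dendritic cells. Lists with at least 5 measured members were tested with camera of limma 3.58.1, which estimates the correlation between genes, and adjusted within each contrast. Members were also adjusted over the list alone.

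Named genes are the 6 largest log2 fold changes each way among genes past the test, with a mean of at least 1 CPM, groups without overlap, and no clone-style, LINC, MIR, SNO, pseudogene-style or uncharacterised name. Added to them are up to 4 members per list by smallest adjusted p, 24 genes named in advance whatever their result, and the 5 largest each way in an interaction.

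Alternatives were DESeq2 1.42.0, RLE factors, no low-count filter, the 2 compared groups alone, the replicate number as a replicate block, each library left out, and limma-trend on log2(FPKM + 1), on log2(FPKM + 0.1) and on log2(FPKM + 1) of all genes above 0. For the interactions all 45 libraries in 1 fit was added, and for lists a preset correlation of 0.01 and the rotation test fry. Chosen after seeing the data were protein-coding genes only, the share of reads on RN7SL genes as a covariate, and fibroblasts without the 3 libraries of lowest RN7SL share. Other splits of the libraries of a contrast into 3 and 3 were also tested.

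The fit was tested on simulated data. Of 100 genes altered 2-fold, 83, 82 and 89 were found in keratinocytes, fibroblasts and dendritic cells, and of 100 altered 1.5-fold 65, 68 and 67, with 12, 6 and 10 false calls. Altered genes had a mean of at least 1 CPM and libraries were drawn independently. Rarer genes and structure shared between libraries are therefore not covered. No read-level step was possible without the reads.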

Results

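Human dendritic cells (DC), primary fibroblasts (FB) and primary keratinocytes (KC) were exposed for 24 h to isolates of skin bacteria or to diluent, and their total RNA was sequenced. The bacteria were Roseomonas mucosa from healthy volunteers (Rm_HV), R. mucosa from people with atopic dermatitis (Rm_AD), Staphylococcus aureus from people with atopic dermatitis (SA_AD) and coagulase-negative staphylococci from healthy volunteers (CoNS_HV). Each of the 15 groups holds 3 libraries, 45 in all. In the staphylococcal groups species and source change together, so a difference between SA_AD and CoNS_HV cannot be given to either. The labels do not say whether the 3 libraries of a group came from separate cultures, so every p-value here measures only the spread between these libraries. Counts are genes past an adjusted p of 0.05, among 16365 measured in keratinocytes, 16881 in fibroblasts and 15280 in dendritic cells. In every gene named as higher or lower in a comparison within a cell type, all 3 libraries of the group lay outside the range of the other group.

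In the main fit dendritic cells responded to every isolate group, keratinocytes to every isolate group with far fewer genes, and fibroblasts to S. aureus. In dendritic cells 4914 genes changed with Rm_HV, 4508 with Rm_AD, 9455 with SA_AD and 8502 with CoNS_HV. Keratinocytes gave 14, 132, 477 and 830 genes in the same order, and fibroblasts 0, 0, 222 and 0. With the replicate number as a block, a pairing the labels do not state, fibroblasts gave 48, 111, 445 and 108. The absence of a fibroblast response to the other groups thus depends on the fit. In keratinocytes the order of SA_AD and CoNS_HV turned without diluent 1 (295 and 115) or diluent 3 (384 and 382). It also turned with all genes above 0 on the FPKM scale (247 and 90). So it did, chosen after seeing the data, with the RN7SL share as a covariate (232 and 33). CoNS_HV gave 201 without CoNS_HV 2 and 238 without CoNS_HV 3. SA_AD was not counted in those fits, so they give no order. A 2-fold or larger difference was met by 1128, 898, 3356 and 2739 of the dendritic cell genes, by 5, 15, 154 and 107 of the keratinocyte genes and by 69 of the fibroblast genes with SA_AD.

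**Figure D1:**
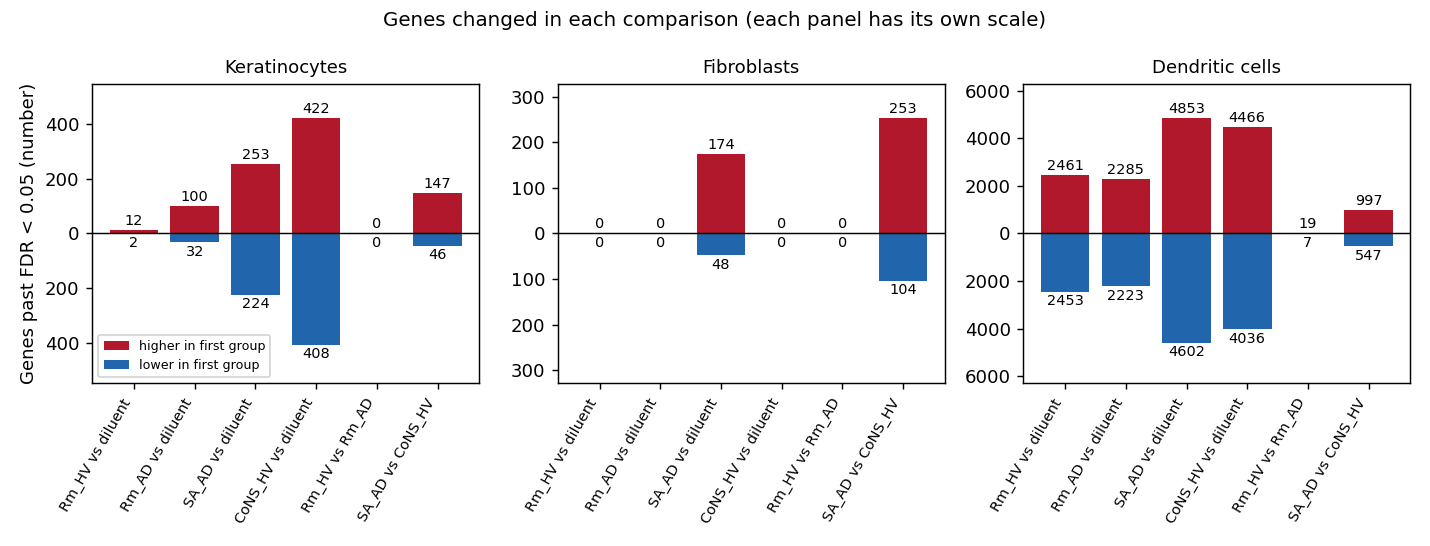
Bars give the number of genes higher (up) and lower (down) at an adjusted p below 0.05 in each comparison, by cell type, with the counts printed on the bars and n = 3 libraries per group. With SA_AD the bars add up to 9455 genes in dendritic cells, 477 in keratinocytes and 222 in fibroblasts.

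**Figure D2:**
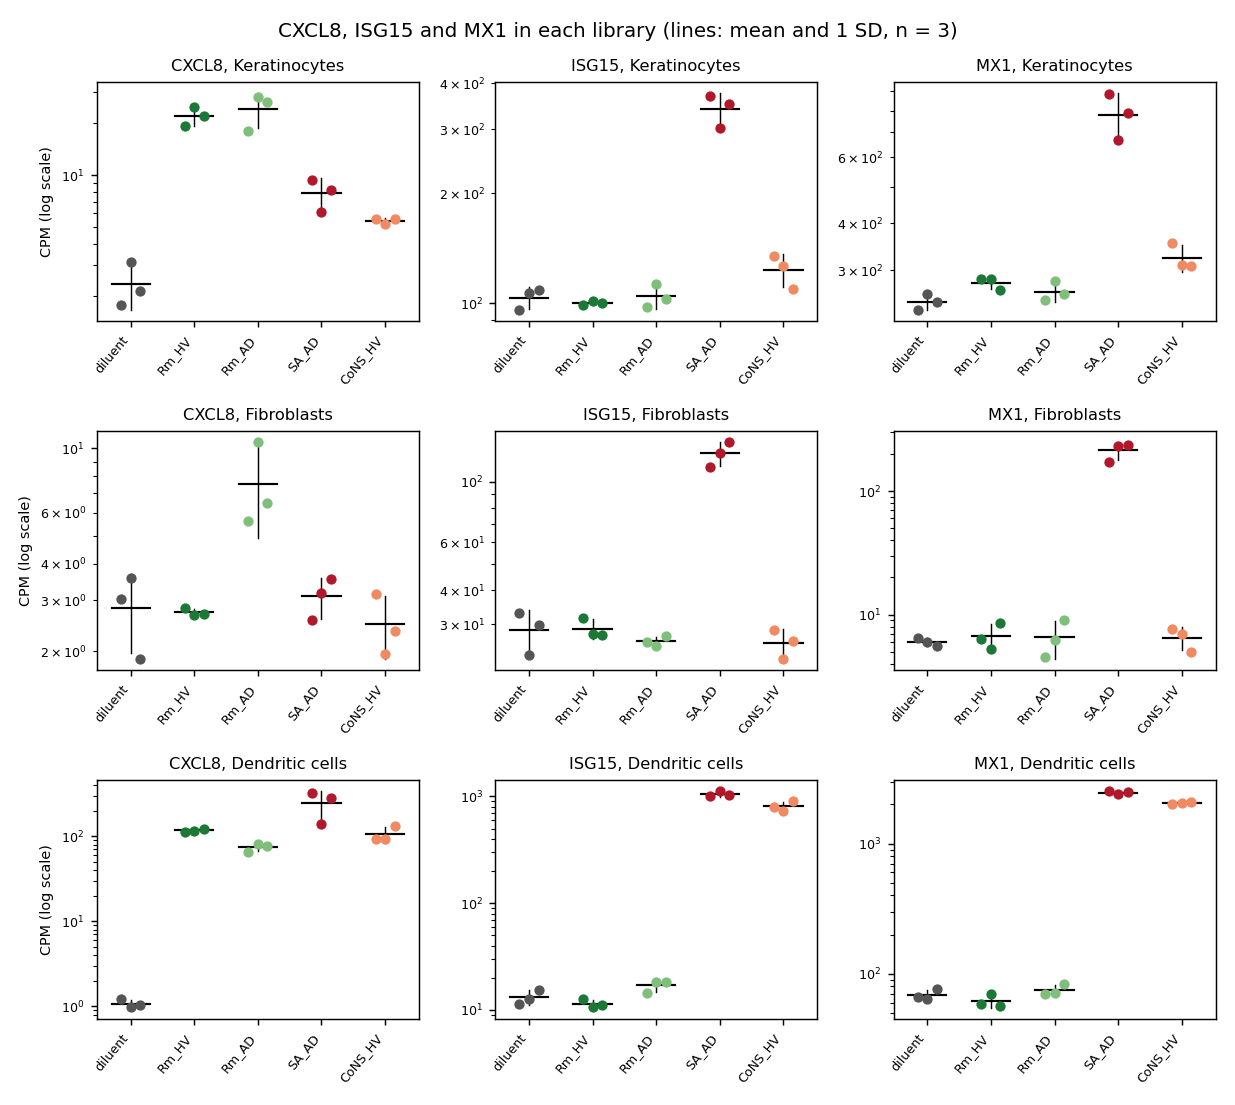
Points are CPM of CXCL8, ISG15 and MX1 in each library on a log axis, with the mean and 1 SD of each group (n = 3), by cell type and condition. Keratinocyte CXCL8 went from 2.36 with diluent to 24.2 with Rm_AD, and fibroblast MX1 from 6.02 with diluent to 214 with SA_AD.

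In keratinocytes, R. mucosa from healthy volunteers was followed by higher transcripts of a small set of early inflammatory genes. CXCL8, which attracts neutrophils, rose from 2.36 ± 0.708 to 22 ± 2.75 CPM (mean ± SD, n = 3 per group), a log2 fold change of 3.25 ± 0.21 (SE, adjusted p = 1.45e-07). CXCL2, another neutrophil attractant, rose 2.85-fold (log2 1.5 ± 0.19) and the leukocyte adhesion molecule ICAM1 rose 1.76-fold (log2 0.81 ± 0.11). SOD2, the mitochondrial superoxide dismutase, rose 1.49-fold (log2 0.58 ± 0.05, adjusted p = 7.76e-06), and TNFAIP3, an inhibitor of NF-kB signalling, rose 1.57-fold (log2 0.65 ± 0.08). TNF itself had a log2 value of 0.98 ± 0.21 with an adjusted p = 0.111, and ISG15 stood at -0.05 ± 0.08 with an adjusted p = 0.933.

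Chemokines, cytokines and NF-kB targets were higher as groups in these keratinocytes, and mesenchymal and matrix genes lower. Of 11 measured chemokines 3 rose and 8 did not pass, with a median log2 of 0.81 and 6 higher when adjusted over the list alone (list adjusted p = 1.3e-05). The TNF and NF-kB response list had 3 of 18 higher (10 when adjusted over the list alone, median 0.23, list adjusted p = 2.5e-05), and the inflammatory cytokines 1 of 15 (8 when adjusted over the list alone, median 0.31, list adjusted p = 0.00013). Antimicrobial peptides and S100 proteins had 0 of 9 past the test over all genes, 6 when adjusted over the list alone, a median of 0.54 and a list adjusted p = 0.006. Proteases, growth factors and wound keratins had 1 of 23 higher (median 0.07, list adjusted p = 0.015), among them SERPINB2, a plasminogen activator inhibitor, which rose 1.36-fold (log2 0.44 ± 0.06). Epidermal differentiation and barrier genes had 0 of 23 past the test (median 0.29, list adjusted p = 0.047). The lists of epithelial-mesenchymal transition (0 of 23 past the test, median -0.14, list adjusted p = 0.006) and of collagens and matrix (0 of 18, median -0.16, list adjusted p = 0.0079) were lower. The 30 interferon-stimulated genes had a median of 0.11 and a list adjusted p = 0.27.

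In all, 14 keratinocyte genes passed with Rm_HV, 12 higher and 2 lower, and 12.6% of measured genes had no overlap between the groups, where 10% would do so by chance. The 14 became 9 without Rm_HV 3, 7 without diluent 1, 9 without diluent 3, 36 (25 higher, 11 lower) with DESeq2, 9 with log2(FPKM + 0.1) or log2(FPKM + 1), and 216 (102 higher, 114 lower) without the low-count filter. With the RN7SL share as a covariate, an alternative chosen after seeing the data, there were 18 (11 higher, 7 lower).

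With R. mucosa from people with atopic dermatitis, keratinocyte chemokine and S100 genes rose, CXCL8 among them. CXCL8 rose to 24.2 ± 5.5 CPM, 10.3-fold over diluent (log2 3.38 ± 0.21, adjusted p = 6.47e-08, n = 3 per group). CCL20, which attracts cells bearing CCR6, rose 6.04-fold (log2 2.62 ± 0.33), CXCL2 rose 3.71-fold (log2 1.88 ± 0.19) and TNFAIP2, a gene induced by TNF, rose 4.18-fold (log2 2.06 ± 0.24). S100A8 and S100A9, which form the antimicrobial protein calprotectin, rose 2.6-fold (log2 1.39 ± 0.2) and 1.84-fold (log2 0.89 ± 0.12). MMP1, the interstitial collagenase, rose 1.37-fold, SERPINB2 rose 1.39-fold and the stress transcription factor ATF3 rose 2.47-fold (log2 1.3 ± 0.18, adjusted p = 0.00124). INHBA, a subunit of activin A, rose 1.36-fold and ADM, which encodes the vasodilator adrenomedullin, rose 1.54-fold.

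The gene groups that were higher with Rm_AD in keratinocytes were NF-kB targets (9 of 18 rose, median 0.34, list adjusted p = 4.2e-05), chemokines (4 of 11, median 0.78, list adjusted p = 4.2e-05), inflammatory cytokines (3 of 15, median 0.58, list adjusted p = 0.0011) and antimicrobial peptides (5 of 9, median 0.67, list adjusted p = 0.0011). Proteases, growth factors and wound keratins followed with 4 of 23 higher (median 0.1, list adjusted p = 0.0015), and barrier genes with 5 of 23 higher, 13 when adjusted over the list alone (median 0.4, list adjusted p = 0.0052). The unfolded protein and amino acid stress list had 5 of 20 higher, 18 when adjusted over the list alone (median 0.3, list adjusted p = 0.043). Collagens and matrix genes were lower as a group (1 of 18 higher, 1 lower, median -0.12, list adjusted p = 0.043). Interferon-stimulated genes had 0 of 30 past the test (list adjusted p = 0.59), and the TNF ligand and receptor families 1 of 14 (list adjusted p = 0.98).

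With Rm_AD 132 keratinocyte genes passed, 100 higher and 32 lower, with 21% of measured genes without overlap against 10% by chance. The 132 became 64, 18 and 44 without Rm_AD 1, 2 and 3, 26, 357 and 28 without diluent 1, 2 and 3, 298 with DESeq2, and 840 (472 higher, 368 lower) without the low-count filter. On the FPKM scale there were 15 (13 higher, 2 lower) with log2(FPKM + 0.1), 17 (13 higher, 4 lower) with log2(FPKM + 1) and 13 when all genes above 0 were kept.

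Set against each other in keratinocytes, the R. mucosa sources gave no gene past the test in the main fit. CXCL8 differed by a log2 of -0.13 ± 0.16 (adjusted p = 0.759, n = 3 per group) and ISG15 by -0.06 ± 0.08 (adjusted p = 0.795). IVL, which encodes involucrin of the cornified envelope, had -0.46 ± 0.17 (adjusted p = 0.293), and HMGCS1, an enzyme of cholesterol synthesis, -0.55 ± 0.16 (adjusted p = 0.264). Of 26 tested lists 0 passed, the smallest adjusted p being 0.17, though 11 of 20 unfolded protein genes and 9 of 20 hypoxia genes were lower with Rm_HV when adjusted over the list alone. In the main edgeR fit 0 genes passed against 2157 at an unadjusted p below 0.05, and DESeq2 gave 9. There was 1 gene without Rm_AD 1, 3 when all genes above 0 were kept on the FPKM scale, and 627 without the low-count filter. Of the 627, 16 were genes the filter had removed. With the replicate number as a block, a pairing the labels do not state, 618 passed (239 higher, 379 lower). The list test with that block called unfolded protein (adjusted p = 0.00079), hypoxia (0.0041) and transition genes (0.017), all lower with Rm_HV.

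S. aureus brought a strong interferon response to keratinocytes. CXCL10, an attractant of T cells, rose from 0.157 ± 0.0368 to 18.9 ± 2.62 CPM, 120-fold (log2 6.83 ± 0.6, adjusted p = 3.94e-07, n = 3 per group), and the related CXCL11 rose 47.5-fold (log2 5.59 ± 0.37). RSAD2, which encodes the antiviral enzyme viperin, rose 38.8-fold (log2 5.3 ± 0.33), IFIT2 rose 14.9-fold and IFIT3 rose 7.66-fold (log2 2.94 ± 0.14). ISG15, a ubiquitin-like modifier, rose from 104 ± 7.06 to 341 ± 35.1 CPM (log2 1.72 ± 0.08, adjusted p = 3.7e-10), and the antiviral GTPase MX1 rose 3.17-fold (log2 1.66 ± 0.08). CXCL8 rose 3.35-fold (log2 1.77 ± 0.23), and the epidermal cytokine IL36G rose 4.14-fold (log2 2.02 ± 0.32). S100A8 rose 2.7-fold, S100A9 rose 2.21-fold and PI3, which encodes the elastase inhibitor elafin, rose 2-fold (log2 0.99 ± 0.14).

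All 30 measured interferon-stimulated genes rose with SA_AD in keratinocytes, with a median log2 of 1.5 and a list adjusted p = 3.1e-06. Chemokines had 6 of 11 higher (median 0.78, list adjusted p = 1.9e-05), NF-kB targets 8 of 18 (median 0.32, list adjusted p = 0.00016) and inflammatory cytokines 5 of 15 (median 0.39, list adjusted p = 0.0013). Antimicrobial peptides had 4 of 9 higher (median 0.69, list adjusted p = 0.002), and proteases, growth factors and wound keratins 3 of 23 (median 0.08, list adjusted p = 0.0069), among them KRT6B, a keratin of wounded epidermis, which rose 1.23-fold. TLR3, a sensor of double-stranded RNA, rose 1.56-fold and MYD88, an adaptor of Toll-like receptors, rose 1.49-fold, while the pattern recognition list did not pass (2 of 13 higher, list adjusted p = 0.057). Epithelial-mesenchymal transition genes (1 higher, 2 lower of 23, median -0.18, list adjusted p = 0.015) and collagens and matrix genes (0 higher, 1 lower of 18, median -0.16, list adjusted p = 0.026) were lower as groups. With the RN7SL share as a covariate, the transition genes had 1 higher and 0 lower (median -0.12), collagens and matrix genes 0 lower (median -0.13), chemokines 3 of 11 higher (median 0.56), NF-kB targets 5 of 18 (median 0.39) and cytokines 3 of 15 (median 0.29). FN1, which encodes fibronectin and is a member of both lower lists, was 1.21-fold lower (log2 -0.27 ± 0.05), a call lost with that covariate.

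Of the 477 keratinocyte genes that passed with SA_AD, 253 were higher and 224 lower, and 175 of the lower ones were non-coding against 49 coding, with 17.3% of measured genes without overlap against 10% by chance. Among the lower genes, POTEE (1.78-fold, log2 -0.83 ± 0.12) and EIF5AL1 (1.48-fold, log2 -0.56 ± 0.09) share reads with close relatives, so their identity is uncertain. RN7SL transcripts, abundant small RNAs, made up 3.8% of reads with SA_AD, 3.51% with CoNS_HV and 4.85% with diluent. The 477 became 316 without SA_AD 2, 295 without diluent 1, 303 with log2(FPKM + 0.1), 304 (170 higher, 134 lower) with log2(FPKM + 1), 247 with all genes above 0 and 768 (370 higher, 398 lower) without the low-count filter. Alternatives chosen after seeing the data gave 281 (222 higher, 59 lower) among protein-coding genes and 232 (171 higher, 61 lower) with the RN7SL share as a covariate, under which the median log2 of the 175 lower non-coding genes went from -0.95 (median SE 0.2) to -0.77 (median SE 0.23).

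Coagulase-negative staphylococci were followed in keratinocytes by higher interferon, barrier and protease genes. CXCL10 rose 18.9-fold (log2 4.1 ± 0.74, adjusted p = 0.0061, n = 3 per group), CXCL11 rose 8.82-fold (log2 3.12 ± 0.44), RSAD2 rose 7.19-fold (log2 2.84 ± 0.36) and IFIT3 rose 2.17-fold (log2 1.12 ± 0.14). ISG15 had a log2 value of 0.25 ± 0.08 and an adjusted p = 0.0742. SPRR2A, a cornified envelope precursor, rose from 3.32 ± 0.602 to 8.84 ± 1.39 CPM (log2 1.42 ± 0.23), SPRR1B of the same family rose 1.63-fold, and KLK7, a protease of skin shedding, rose 1.38-fold. S100A9 rose 2.02-fold (log2 1.02 ± 0.12, adjusted p = 0.000512), the gelatinase gene MMP9 rose 2.2-fold (log2 1.14 ± 0.19) and MMP1 rose 1.28-fold. STARD4, which carries sterols, rose 1.33-fold and MSMO1, a cholesterol synthesis enzyme, rose 1.25-fold. IL1B, which encodes interleukin-1 beta, rose 1.21-fold. With the RN7SL share as a covariate, chosen after seeing the data, the IL1B call was lost (0 of 15 cytokines higher). At most 1 of SPRR2A, SPRR1B and KLK7 kept its call (1 of 23 barrier genes higher). The same held for MMP9 and MMP1 (1 of 23 proteases higher).

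As groups with CoNS_HV in keratinocytes, chemokines (6 of 11 higher, median 0.68, list adjusted p = 0.0018), antimicrobial peptides (4 of 9, median 0.74, list adjusted p = 0.01) and NF-kB targets (5 of 18, median 0.26, list adjusted p = 0.015) passed. So did interferon-stimulated genes (17 of 30 higher, median 0.36, list adjusted p = 0.029), proteases, growth factors and wound keratins (6 of 23, list adjusted p = 0.038), barrier genes (7 of 23, median 0.38, list adjusted p = 0.043) and inflammatory cytokines (3 of 15, list adjusted p = 0.044). Of 20 unfolded protein and amino acid stress genes 10 rose, 15 when adjusted over the list alone, with a median of 0.33 and a list adjusted p = 0.12. Cholesterol synthesis genes had 5 of 22 higher (list adjusted p = 0.28). Epithelial-mesenchymal transition genes had 3 higher and 3 lower of 23 (list adjusted p = 0.94). With the RN7SL share as a covariate, chosen after seeing the data, fewer members were called and the list test was not run: 1 of 11 chemokines (median 0.67), 2 of 9 antimicrobial peptides (median 0.6), 0 of 18 NF-kB targets (median 0.28), 4 of 30 interferon-stimulated genes (median 0.37), 1 of 23 proteases, 1 of 23 barrier genes (median 0.45), 0 of 15 cytokines (median 0.13), 1 of 20 unfolded protein genes (median 0.38), 1 of 22 cholesterol synthesis genes, and 1 higher and 0 lower of the transition genes.

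With CoNS_HV 830 keratinocyte genes passed, 422 higher and 408 lower, 216 of the lower ones coding and 192 non-coding, and 24.5% of measured genes had no overlap against 10% by chance. The 830 became 201 without CoNS_HV 2, 238 without CoNS_HV 3, 115 without diluent 1, 382 without diluent 3, 316 with log2(FPKM + 0.1), 310 with log2(FPKM + 1), 90 with all genes above 0 and 1472 (723 higher, 749 lower) without the low-count filter. With the RN7SL share as a covariate, chosen after seeing the data, 33 passed (26 higher, 7 lower), 32 of them among the 830. Under it the median log2 of the 192 lower non-coding genes went from -0.87 (median SE 0.2) to -0.68 (median SE 0.25).

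Between the staphylococcal groups, keratinocytes had higher interferon genes with SA_AD. CXCL10 was 6.37-fold higher with SA_AD than with CoNS_HV (log2 2.73 ± 0.39, adjusted p = 0.000376, n = 3 per group), RSAD2 was 5.4-fold higher (log2 2.46 ± 0.25), and CMPK2, a mitochondrial nucleotide kinase induced by interferon, stood at 70.5 ± 14.8 against 17.7 ± 5.42 CPM (log2 2.01 ± 0.16). ISG15 was 2.76-fold higher (log2 1.47 ± 0.08, adjusted p = 7.29e-09), MX1 was 2.41-fold higher and TLR3 was 1.64-fold higher. CXCL8 differed by a log2 of 0.54 ± 0.2 (adjusted p = 0.256) and IL1B by 0.01 ± 0.04 (adjusted p = 0.959). Of 30 interferon-stimulated genes 28 were higher (median 1.08, list adjusted p = 1.9e-05), as were 2 of 11 chemokines (median 0.34, list adjusted p = 0.01) and 2 of 18 NF-kB targets (median 0.16, list adjusted p = 0.03), while the transition genes were lower (0 higher, 2 lower of 23, median -0.08, list adjusted p = 0.018). In all 193 genes passed, 147 higher and 46 lower. The 193 became 117 without CoNS_HV 2, 123 without SA_AD 1, 119 without SA_AD 3, 293 (181 higher, 112 lower) with DESeq2, and 583 without the low-count filter. On the FPKM scale there were 89 (87 higher, 2 lower), 90 (87 higher, 3 lower) and 83 (78 higher, 5 lower).

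Several gene groups gave no list call by camera in any keratinocyte comparison with diluent. With Rm_HV these were type 2 and itch mediators (0 of 10 past the test, median 0.07, list adjusted p = 0.27), epidermal lipid synthesis (0 of 19, median 0.03, list adjusted p = 0.27), cholinergic signalling (0 of 8, list adjusted p = 0.64) and prostaglandins and eicosanoids (0 of 11, list adjusted p = 0.69). Hypoxia and glycolysis (1 of 20 higher), oxidative and metal stress (0 of 20), cell cycle (0 of 22, list adjusted p = 0.89), replication-dependent histones (0 of 12, list adjusted p = 0.77) and dendritic cell maturation genes (0 of 12, list adjusted p = 0.64) did not pass either. The mitochondrial transcripts that mark RNA quality had 0 of 15 past the test (list adjusted p = 0.77), and 0.53 with SA_AD. Markers of keratinocytes (0 of 12, list adjusted p = 0.77), fibroblasts (0 of 6, median -0.17, list adjusted p = 0.43) and melanocytes (0 of 6, median 0.31, list adjusted p = 0.27) were likewise without a call. TSLP, IL33 and FLG, genes tied to atopic skin, had adjusted p values of 0.821, 0.513 and 0.926 with SA_AD. The rotation test fry, which called more lists, did call some of these groups. It gave an adjusted p of 0.0039 for type 2 and itch mediators with Rm_AD and 0.0064 for epidermal lipid synthesis with CoNS_HV. The lymphocyte marker list had fewer than 5 measured members in every cell type and was not tested.

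Fibroblasts gave no gene past the test in the main fit with either R. mucosa source or with coagulase-negative staphylococci. CXCL8 had a log2 value of 1.44 ± 0.26 with Rm_AD (7.54 ± 2.62 against 2.83 ± 0.863 CPM, adjusted p = 0.379, n = 3 per group), -0.03 ± 0.28 with Rm_HV and -0.14 with CoNS_HV. Between the R. mucosa sources fibroblast CXCL8 differed by -1.47 ± 0.25 (adjusted p = 0.18), and ISG15 had -0.15 ± 0.12 with CoNS_HV (adjusted p = 0.827). The TNF and NF-kB response list had 0 of 18 members past the test in all 6 fibroblast comparisons. No list passed with Rm_HV (smallest adjusted p = 0.9), Rm_AD (0.82), CoNS_HV (0.93) or between the R. mucosa sources (0.56), where 15 of 22 cholesterol synthesis genes were higher with Rm_HV when adjusted over the list alone (median 0.21).

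With edgeR the counts of 0 in fibroblasts stood beside 977 genes at an unadjusted p below 0.05 with Rm_HV (DESeq2 3), 1202 with Rm_AD (DESeq2 1), 1014 with CoNS_HV (DESeq2 1) and 2106 between the R. mucosa sources (DESeq2 15). The smallest adjusted p values over all genes were 0.49, 0.379, 0.799 and 0.18. Without the low-count filter the counts were 263, 265, 262 and 690, and with all genes above 0 on the FPKM scale 1, 7, 6 and 6. Of the genes called without the filter, 15, 10, 13 and 18 were ones it had removed, so most had been tested in the main fit. With the 2 groups alone they were 1 for Rm_HV, 2 for Rm_AD and 1 for CoNS_HV, which also gave 1 with log2(FPKM + 0.1) and log2(FPKM + 1). There was 1 gene with Rm_AD without Rm_AD 1, and 1 between the R. mucosa sources without Rm_AD 2. The replicate block, a pairing the labels do not state, gave 48 with Rm_HV, 111 with Rm_AD, 108 with CoNS_HV and 662 between the R. mucosa sources.

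S. aureus was followed in fibroblasts by higher transcripts of the whole measured interferon list. MX1 rose from 6.02 ± 0.468 to 214 ± 35.7 CPM, 35.5-fold (log2 5.16 ± 0.19, adjusted p = 5.61e-12, n = 3 per group). RSAD2 rose 35.8-fold (log2 5.22 ± 0.34), IFI44L rose 20.8-fold (log2 4.36 ± 0.19), OAS1, which makes the activator of ribonuclease L, rose 17.3-fold (log2 4.07 ± 0.18), and IFIT1, which binds foreign RNA caps, rose 9.86-fold (log2 3.3 ± 0.11). ISG15 rose 4.45-fold (log2 2.15 ± 0.11, adjusted p = 5.16e-10). HMOX1, the haem-degrading oxygenase, rose from 100 ± 11.5 to 180 ± 10.6 CPM (log2 0.85 ± 0.15), MYD88 rose 1.91-fold and TLR3 rose 1.48-fold. CXCL8 had a log2 value of 0.15 ± 0.27 (adjusted p = 0.91) and MMP3, the matrix protease stromelysin, 0.7 ± 0.17 (adjusted p = 0.0589). THBS1, the matrix protein thrombospondin, was 1.19-fold lower (log2 -0.25 ± 0.05). Lower histone genes included HIST1H2BB (1.96-fold, log2 -0.98 ± 0.17) and HIST1H4L (1.64-fold, log2 -0.71 ± 0.09), whose reads are shared with paralogs, so their identity is uncertain.

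All 30 interferon-stimulated genes rose in fibroblasts with SA_AD (median log2 2.1, list adjusted p = 1e-07), and no other of 26 lists passed. Chemokines had 3 of 13 higher (median 0.12, list adjusted p = 0.15), replication-dependent histones 3 of 12 lower (7 when adjusted over the list alone, median -0.35, list adjusted p = 0.25) and oxidative and metal stress 3 of 20 higher (list adjusted p = 0.48). Collagens and matrix genes had 1 of 24 lower (6 when adjusted over the list alone, list adjusted p = 0.25), and the TNF families 1 of 14 higher (list adjusted p = 0.48). With the RN7SL share as a covariate, 29 of 30 interferon-stimulated genes (median 1.93), 1 of 13 chemokines and 0 of 20 oxidative stress genes were higher, and 0 of 12 histones lower (median -0.19). RN7SL transcripts made up 1.46% and 1.53% of reads in SA_AD libraries 2 and 3 and 2.3% in diluent library 1, the lowest shares in fibroblasts. In all 222 genes passed, 174 higher and 48 lower. The 222 became 146 without diluent 3, 222 (150 higher, 72 lower) without diluent 1, 129 (120 higher, 9 lower) with all genes above 0 on the FPKM scale and 608 (354 higher, 254 lower) without the low-count filter. Alternatives chosen after seeing the data gave 111 (102 higher, 9 lower) with the RN7SL share as a covariate and 87 (76 higher, 11 lower) without the 3 libraries of lowest RN7SL share, which leaves 1 SA_AD library, assumed to vary like the other groups.

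Against coagulase-negative staphylococci, fibroblasts with S. aureus again had higher interferon genes. MX1 stood at 214 ± 35.7 against 6.51 ± 1.36 CPM (log2 5.03 ± 0.18, adjusted p = 4.5e-12, n = 3 per group), OAS1 was 20.4-fold higher, IFIT1 was 8.92-fold higher and ISG15 was 4.97-fold higher (log2 2.3 ± 0.11). MMP3 was 2.07-fold higher (log2 1.05 ± 0.17, adjusted p = 0.00194), HMOX1 was 1.94-fold higher (log2 0.95 ± 0.15), FTH1, the ferritin heavy chain, was 1.18-fold higher and TLR3 was 1.53-fold higher. Lower with SA_AD were SCARNA6, a small RNA of the Cajal body (3.43-fold, log2 -1.77 ± 0.26), HIST1H4C (1.71-fold, log2 -0.77 ± 0.14) and THBS1 (1.24-fold, log2 -0.31 ± 0.05). Small non-coding RNAs made up 5.48%, 2.56% and 2.74% of reads in SA_AD libraries 1, 2 and 3. In CoNS_HV they made up 6.45%, 6.75% and 5.36%. For SCARNA6 an effect of S. aureus cannot be told apart from this lower share. Of the lists the interferon-stimulated genes passed, 30 of 30 higher (median 2.2, list adjusted p = 1.7e-07). Histones had 7 of 12 lower (median -0.46, list adjusted p = 0.14), chemokines 3 of 13 higher (list adjusted p = 0.067) but 0 higher without the 3 libraries of lowest RN7SL share, where 1 SA_AD library is left, and cholesterol synthesis genes 2 of 22 higher, 16 when adjusted over the list alone (median 0.23, list adjusted p = 0.2). With the RN7SL share as a covariate, 29 of 30 interferon-stimulated genes (median 2.06), 1 of 13 chemokines and 0 of 22 cholesterol synthesis genes were higher, and 1 of 12 histones lower (median -0.26). Markers of endothelial cells (0 of 5 past the test, median 0.76, list adjusted p = 0.18) gave no call.

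The comparison held 357 genes, 253 higher and 104 lower. They became 189 without CoNS_HV 2, 208 without CoNS_HV 3, 220 without SA_AD 1, 174 without SA_AD 3, 167 (144 higher, 23 lower) with log2(FPKM + 0.1) or log2(FPKM + 1), 132 (121 higher, 11 lower) with all genes above 0 and 909 without the low-count filter. Alternatives chosen after seeing the data gave 120 (109 higher, 11 lower) with the RN7SL share as a covariate and 134 (113 higher, 21 lower) without the 3 libraries of lowest RN7SL share, with 1 SA_AD library left and assumed to vary like the other groups.

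In dendritic cells, R. mucosa from healthy volunteers was followed by higher cytokine and TNF family transcripts and lower division genes. CXCL8 rose from 1.07 ± 0.12 to 117 ± 5.42 CPM, 109-fold (log2 6.76 ± 0.34, adjusted p = 3.31e-12, n = 3 per group), and TNF rose from 0.778 ± 0.0928 to 13.7 ± 1.4 (log2 4.13 ± 0.23). IL1B rose 23.1-fold and IL6, the acute-phase cytokine, rose 17.2-fold. TNFAIP6, which binds hyaluronan, rose 176-fold (log2 7.41 ± 0.31), and CXCL5 was at least 26.3-fold and EBI3, a subunit of interleukins 27 and 35, at least 25.8-fold above a diluent group without reads. CCL20 was 469-fold higher with a 95% counting interval of 83.2 to 18500. SOD2 rose from 406 ± 2.82 to 4750 ± 148 CPM (log2 3.55 ± 0.05, adjusted p = 1.16e-20), and BIRC3, an inhibitor of cell death, rose 16.5-fold. MS4A6A, a membrane protein of myeloid cells, was 9.56-fold lower (log2 -3.25 ± 0.17), P2RY12, a nucleotide receptor, was 14.2-fold lower, and the scavenger receptor CD163 was 3.52-fold lower (log2 -1.82 ± 0.13). All such floors and intervals cover counting error only.

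Of 20 NF-kB targets 19 rose with Rm_HV in dendritic cells (median 1.7, list adjusted p = 9.6e-05), as did 12 of 16 inflammatory cytokines, with 2 lower (median 2.29, list adjusted p = 0.023). The TNF families had 10 higher and 2 lower of 20 (median 0.29, list adjusted p = 9.6e-05), among them TNFRSF9, a costimulatory receptor, which rose 57.5-fold. Oxidative and metal stress genes had 16 of 21 higher (median 0.56, list adjusted p = 0.00014), such as SLC7A11, the cystine carrier, which rose 3.94-fold (log2 1.98 ± 0.05). All 22 cell cycle genes were lower (median -1.44, list adjusted p = 0.00014), with TOP2A, a topoisomerase of dividing cells, 3.63-fold lower, and 11 of 12 histone genes fell (median -1.53, list adjusted p = 0.0072). Myeloid markers had 1 higher and 12 lower of 16 (median -0.97, list adjusted p = 0.019), and transition genes 7 higher and 4 lower of 17 (median 0.05, list adjusted p = 0.019). Chemokines had 16 higher and 2 lower of 23 (median 1.76, list adjusted p = 0.096). Interferon-stimulated genes had 4 higher and 9 lower of 30, with a median of -0.12, a mean of 0.01 and a list adjusted p = 0.82, and ISG15 had -0.2 ± 0.13 (adjusted p = 0.271). Maturation genes had 10 higher and 9 lower of 24 (list adjusted p = 0.3), a balance that became 9 and 10 on the FPKM scale, although LAMP3, a lysosomal marker of mature cells, rose 11.7-fold.

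Of the 4914 genes, 2461 were higher and 2453 lower, a near-even balance that DESeq2 turned (2247 higher, 2364 lower). They became 3253 (1389 higher, 1864 lower) with log2(FPKM + 0.1) and 3107 (1256 higher, 1851 lower) with all genes above 0 on that scale.

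R. mucosa from people with atopic dermatitis was followed in dendritic cells by higher cytokines and oxidative stress genes and lower division genes. CXCL8 rose 69.9-fold (log2 6.12 ± 0.35, adjusted p = 3.52e-11, n = 3 per group), IL6 rose 24.9-fold, IL1B rose 20.6-fold and TNF rose 9.47-fold (log2 3.24 ± 0.25). CXCL5 was at least 48.3-fold above a diluent group without reads, and CCL20 was 221-fold higher with a 95% counting interval of 38.9 to 8700. SOD2 rose 9.96-fold (log2 3.32 ± 0.05), TNFSF15, a TNF family ligand, rose 6.95-fold (log2 2.8 ± 0.09) and MT1G, which binds metals, rose 4.05-fold. IFI6, an interferon-induced mitochondrial protein, rose from 48.1 ± 1.45 to 78.1 ± 7.74 CPM (log2 0.7 ± 0.06, adjusted p = 3.55e-08). P2RY12 was 15.5-fold, MS4A6A 7.53-fold and CD163 3.01-fold lower.

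The called groups of dendritic cells with Rm_AD were NF-kB targets (19 of 20 higher, median 1.43, list adjusted p = 0.00015), TNF families (9 higher, 1 lower of 20, list adjusted p = 0.00018), oxidative and metal stress (18 of 21 higher, median 0.57, list adjusted p = 0.00015), transition genes (8 higher, 3 lower of 17, list adjusted p = 0.01) and inflammatory cytokines (9 higher, 2 lower of 16, median 1.83, list adjusted p = 0.035). Lower were cell cycle genes (22 of 22, median -1.37, list adjusted p = 0.00018), histones (11 of 12, median -1.37, list adjusted p = 0.01) and myeloid markers (2 higher, 10 lower of 16, median -0.74, list adjusted p = 0.032). Interferon-stimulated genes had 11 higher and 6 lower of 30 (median 0.13, list adjusted p = 0.76). Chemokines had 17 higher and 1 lower of 23 (median 2.75, or 2.06 with genes absent from a group at their bound, list adjusted p = 0.068). Prostaglandins and eicosanoids had 6 higher and 5 lower of 15 (list adjusted p = 0.89), a balance of 4 and 5 on the FPKM scale. In all 4508 genes passed, 2285 higher and 2223 lower, a balance that DESeq2 turned (2078 higher, 2187 lower). They became 2882 (1237 higher, 1645 lower) with log2(FPKM + 0.1), 2975 (1221 higher, 1754 lower) with log2(FPKM + 1) and 2650 (1061 higher, 1589 lower) with all genes above 0.

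Between the R. mucosa sources, dendritic cells had more transcript of TNF family genes with Rm_HV, and more of SIGLEC1, IFI6 and OAS3 with Rm_AD, while the interferon list as a whole did not pass. TNFSF15 stood at 81.5 ± 7.11 against 42.5 ± 1.35 CPM, 1.92-fold higher with Rm_HV (log2 0.94 ± 0.07, adjusted p = 2.55e-07, n = 3 per group). TNFRSF4, the costimulatory receptor OX40, was 1.91-fold higher (log2 0.94 ± 0.11), and TRAF1, an adaptor of TNF receptors, was 1.41-fold higher (log2 0.49 ± 0.06). TNF was 1.86-fold higher (log2 0.89 ± 0.16, adjusted p = 0.023), a call lost without Rm_AD 1 or Rm_AD 3 (0.79 each) or Rm_HV 3 (0.81). SIGLEC1, a sialic acid receptor induced by interferon, was 2.8-fold lower with Rm_HV (7.48 ± 2.01 against 20.9 ± 3.94 CPM, log2 -1.48 ± 0.17, adjusted p = 0.000372). IFI6 was 1.42-fold lower (log2 -0.51 ± 0.06) and OAS3, of the same family as OAS1, 1.41-fold lower (log2 -0.49 ± 0.07). ISG15 had -0.56 ± 0.13 with an adjusted p = 0.0796, and CXCL8 0.64 ± 0.2 with an adjusted p = 0.275.

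**Figure D3:**
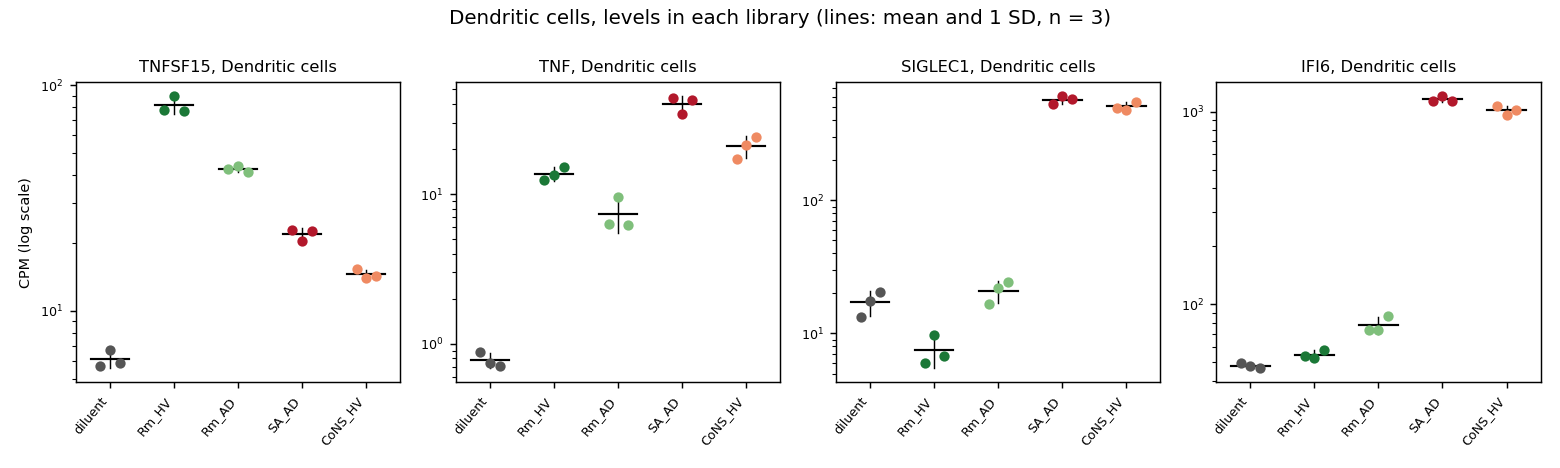
Points are CPM of TNFSF15, TNF, SIGLEC1 and IFI6 in each dendritic cell library by condition, with the mean and 1 SD of each group (n = 3). With Rm_HV and Rm_AD the means were 81.5 and 42.5 for TNFSF15 and 7.48 and 20.9 for SIGLEC1.

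The TNF families passed as a group in this comparison, with 4 of 20 higher and 6 when adjusted over the list alone (median 0.11, list adjusted p = 0.00052), and so did NF-kB targets, with 6 of 20 higher and 14 when adjusted over the list alone (median 0.22, list adjusted p = 0.011). Interferon-stimulated genes had 2 of 30 lower, 10 when adjusted over the list alone, with a median of -0.17 and a list adjusted p = 0.065. In all 26 genes passed, 19 higher and 7 lower. The 26 became 8, 11 and 15 without Rm_AD 1, 2 and 3, 12 without Rm_HV 1, 7 (3 higher, 4 lower) without Rm_HV 3, 98 with DESeq2, 73 with the 2 groups alone and 288 (135 higher, 153 lower) without the low-count filter. On the FPKM scale there were 6 (3 higher, 3 lower) with log2(FPKM + 0.1), 8 (5 higher, 3 lower) with log2(FPKM + 1) and 13 (7 higher, 6 lower) with all genes above 0.

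S. aureus brought the largest response of the series, in dendritic cells, with interferon genes, chemokines and maturation genes higher and division genes lower. CXCL10 went from no reads to 609 ± 200 CPM, at least 4350-fold (adjusted p = 1.47e-15, n = 3 per group), and ISG15 rose from 13.1 ± 2.1 to 1060 ± 63.3 (log2 6.33 ± 0.11, adjusted p = 1.1e-20). CCL8, a monocyte attractant, rose 5510-fold (log2 12.34 ± 0.29), TNF rose 51.5-fold (log2 5.67 ± 0.2), IL6 rose 364-fold and IL1B rose 121-fold. IDO1, which breaks down tryptophan, rose 2590-fold, TNFSF10, the death ligand TRAIL, rose 193-fold, and the costimulatory receptor CD40 rose 5.8-fold. TLR2, a receptor of bacterial lipoproteins, rose 3.24-fold and TLR5, the flagellin receptor, was 2.29-fold lower. HJURP, a centromere chaperone, was 113-fold lower (log2 -6.77 ± 0.28), RRM2, which makes deoxynucleotides, 49.1-fold lower (log2 -5.61 ± 0.12) and MKI67, a marker of cycling cells, 20.2-fold lower.

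All 30 interferon-stimulated genes (median 4.85, list adjusted p = 4.9e-05), 23 of 23 chemokines (median 5.28, list adjusted p = 0.043) and 20 of 20 NF-kB targets (median 2.51, list adjusted p = 0.0014) rose with SA_AD in dendritic cells. TNF families had 14 higher and 5 lower of 20 (median 2.19, list adjusted p = 0.0012), oxidative and metal stress 17 higher and 2 lower of 21 (median 1, list adjusted p = 0.0025), maturation genes 18 higher and 2 lower of 24 (median 1.07, list adjusted p = 0.028) and transition genes 11 higher and 5 lower of 17 (median 0.7, list adjusted p = 0.043). Cell cycle genes fell, 22 of 22 (median -4.26, list adjusted p = 0.00064), as did 11 of 12 histones (median -2.79, list adjusted p = 0.013). Inflammatory cytokines had 12 higher and 2 lower of 16 (median 4.05, or 3.63 with genes absent from a group at their bound, list adjusted p = 0.056), and cholesterol synthesis 3 higher and 16 lower of 21 (median -0.37, list adjusted p = 0.06). Unfolded protein genes had 7 higher and 6 lower of 20 (list adjusted p = 0.79), and 4 and 8 on the FPKM scale. Myeloid markers had 6 higher and 5 lower of 16 (list adjusted p = 0.79), and 5 and 7 on that scale. Pattern recognition receptors had 15 higher and 5 lower of 21 (list adjusted p = 0.26). Of the 9455 genes 4853 were higher and 4602 lower, against 7744 (2405 higher, 5339 lower) with log2(FPKM + 0.1), 7764 (2417 higher, 5347 lower) with log2(FPKM + 1) and 8495 (2702 higher, 5793 lower) with all genes above 0.

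Coagulase-negative staphylococci were followed in dendritic cells by higher interferon genes and chemokines and lower division genes. CXCL10 was at least 1700-fold above a diluent group without reads, at 238 ± 43.6 CPM (n = 3 per group), and ISG15 rose 61.6-fold to 808 ± 87.7 (log2 5.94 ± 0.11). CCL8 rose 2550-fold, TNFSF10 rose 104-fold, IL6 rose 140-fold, IL1B rose 52.3-fold and TNF rose 26.8-fold. IDO1 rose 945-fold, CD274, the checkpoint ligand PD-L1, rose 4.93-fold and CD40 rose 3.88-fold. TOP2A was 29.5-fold lower and HPGDS, a prostaglandin D synthase, 7.06-fold lower. The matrix proteases MMP14 and MMP9 rose 8.99-fold and 7.7-fold.

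Called higher as groups were interferon-stimulated genes (30 of 30 higher, median 4.45, list adjusted p = 1.7e-05), chemokines (23 of 23, median 4.18, or 3.36 with genes absent from a group at their bound, list adjusted p = 0.033), NF-kB targets (20 of 20, median 2.16, list adjusted p = 0.00096), TNF families (13 higher, 3 lower of 20, median 1.44, list adjusted p = 0.00096), oxidative and metal stress (16 higher, 2 lower of 21, median 1.01), maturation (18 higher, 2 lower of 24, median 0.83, list adjusted p = 0.033) and transition genes (11 higher, 4 lower of 17, median 0.51). Cell cycle genes (22 of 22 lower, median -3.89, list adjusted p = 0.00046) and histones (11 of 12, median -2.52, list adjusted p = 0.015) fell. Inflammatory cytokines had 12 higher and 2 lower of 16 (median 2.88, or 2.08 with genes absent from a group at their bound, list adjusted p = 0.078). Epidermal lipid synthesis had 6 higher and 5 lower of 15 (list adjusted p = 0.7), and 2 and 6 on the FPKM scale. Of the 8502 dendritic cell genes 4466 were higher and 4036 lower, against 6848 (2216 higher, 4632 lower) with log2(FPKM + 0.1), 6866 (2210 higher, 4656 lower) with log2(FPKM + 1) and 7276 (2361 higher, 4915 lower) with all genes above 0.

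Between the staphylococcal groups, dendritic cells had higher inflammatory and maturation genes with SA_AD. CXCL9, an attractant of T cells, stood at 13.6 ± 6.09 against 1.43 ± 0.178 CPM (log2 3.25 ± 0.34, adjusted p = 2.85e-05, n = 3 per group), and IL12B, the shared subunit of interleukins 12 and 23, at 55.6 ± 8.53 against 13.9 ± 2.22 (log2 2 ± 0.13). PTGS2, the inducible cyclooxygenase, was 3.42-fold higher, CCR7, the lymph node homing receptor, 3.13-fold higher and IDO1 2.74-fold higher. IL6 was 2.6-fold higher (log2 1.38 ± 0.22), TNF 1.92-fold higher (log2 0.94 ± 0.13, adjusted p = 0.000109) and ISG15 1.31-fold higher (log2 0.39 ± 0.08). UHRF1, a replication factor of DNA methylation, was 2.43-fold lower (log2 -1.28 ± 0.17) and GPR34, a lysophospholipid receptor, 2.34-fold lower. Called lists were TNF families (10 higher, 2 lower of 20, median 0.38, list adjusted p = 0.0055), cytokines (12 higher, 1 lower of 16, median 0.9, list adjusted p = 0.0077), interferon-stimulated genes (25 of 30 higher, median 0.38, list adjusted p = 0.0077), NF-kB targets (16 of 20 higher, median 0.34, list adjusted p = 0.013), maturation (12 higher, 1 lower of 24, list adjusted p = 0.028) and hypoxia and glycolysis (3 of 19 higher, median 0.1, list adjusted p = 0.046). Chemokines had 13 higher and 1 lower of 23 (median 0.81, list adjusted p = 0.074).

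In all 1544 dendritic cell genes differed between SA_AD and CoNS_HV, 997 higher and 547 lower, and 116 by 2-fold or more. They became 900 without CoNS_HV 1, 889 without SA_AD 1, 817 without SA_AD 3, 927 with the 2 groups alone, 580 (238 higher, 342 lower) with log2(FPKM + 0.1), 640 (313 higher, 327 lower) with log2(FPKM + 1) and 321 (168 higher, 153 lower) with all genes above 0.

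**Figure D4:**
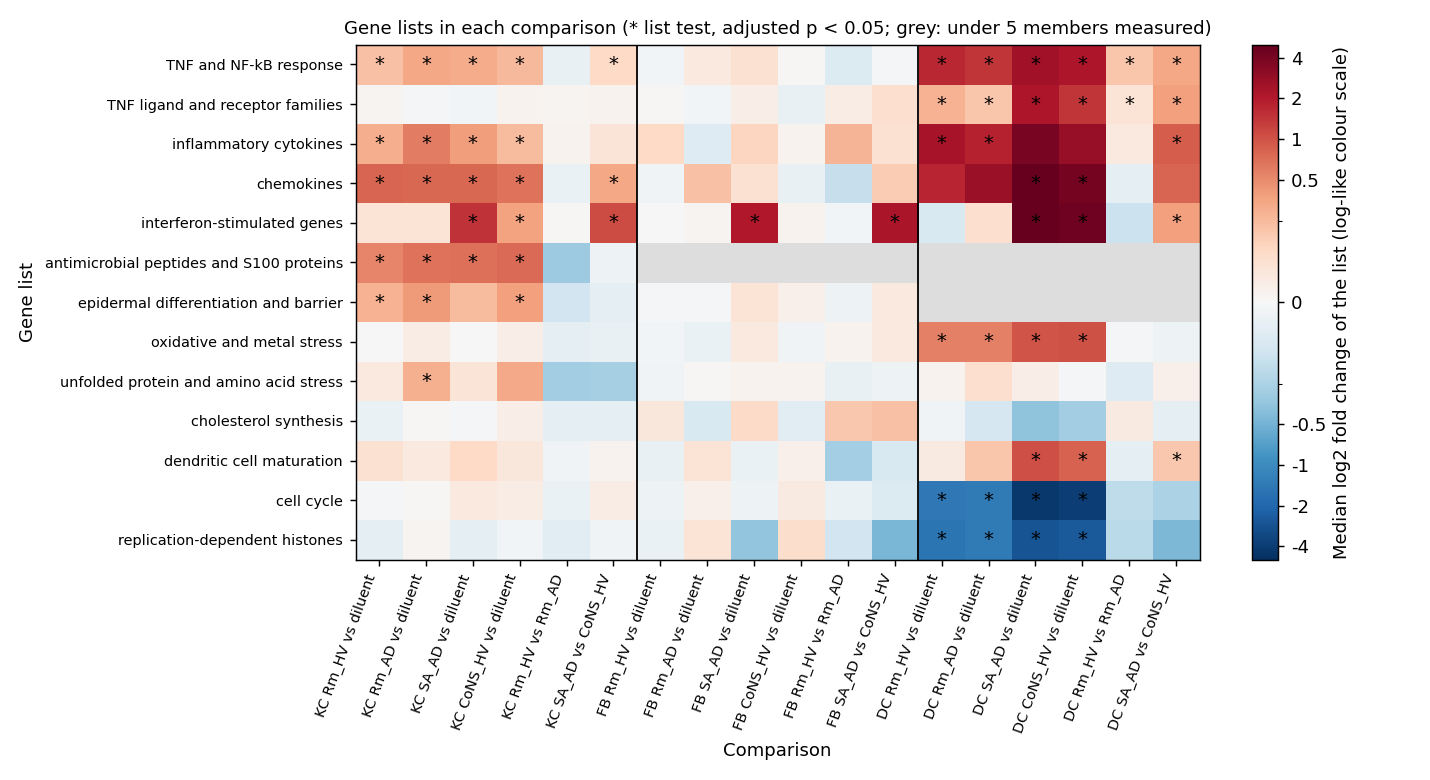
Cells give the median log2 fold change of the measured members of a selection of the gene lists (rows) in each comparison (columns, n = 3 libraries per group), with an asterisk where the list passed at an adjusted p below 0.05 and grey where fewer than 5 members were measured. Interferon-stimulated genes had medians of 4.85 in dendritic cells, 2.1 in fibroblasts and 1.5 in keratinocytes with SA_AD.

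Across the series 79 of 444 list tests passed. All 79 also passed with a preset correlation of 0.01 and with a rotation test. That is little support, since these called 94 and 87 further lists. The replicate block kept 74 of the 79. The median, the mean and the test of a list differed in sign in 70 of the 444 tests and in 0 of the 79 that passed.

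Whether the R. mucosa sources differ more in one cell type than in another was tested gene by gene over 18656 genes in 18 libraries. CXCL8 stood apart between fibroblasts and dendritic cells: Rm_HV over Rm_AD gave a log2 of -1.45 in fibroblasts and 0.65 in dendritic cells, a difference of -2.09 ± 0.28 (adjusted p = 0.00413, n = 3 per group). INHBA had -0.28 in keratinocytes and 0.38 in dendritic cells, a difference of -0.65 ± 0.09 (adjusted p = 0.00444), lost with all 45 libraries fitted together (-0.66). In all 2 genes differed between fibroblasts and dendritic cells, 4 between keratinocytes and dendritic cells, and 0 between keratinocytes and fibroblasts with edgeR, where 1684 had an unadjusted p below 0.05 and DESeq2 gave 98. The replicate block gave 84, 64 and 161 in that order. DESeq2 gave 64 for fibroblasts and dendritic cells and 86 for keratinocytes and dendritic cells, all 45 libraries in 1 fit gave 13, 14 and 1, and leaving the low-count filter out gave 299 (209 higher, 90 lower, where the 2 genes of the main test were lower), 317 and 316.

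Single libraries moved these counts of differing genes. For fibroblasts and dendritic cells there was 1 gene without DC Rm_AD 2, DC Rm_AD 3, DC Rm_HV 1, DC Rm_HV 3, FB Rm_AD 2, FB Rm_HV 1 or FB Rm_HV 3, 4 without DC Rm_HV 2, 7 without FB Rm_AD 1 and 70 (45 higher, 25 lower) without FB Rm_HV 2. For keratinocytes and dendritic cells there was 1 without DC Rm_AD 3, KC Rm_AD 2, KC Rm_AD 3 or KC Rm_HV 1, 2 without DC Rm_AD 1, DC Rm_HV 1 or DC Rm_HV 3, 8 without DC Rm_HV 2 and 30 without KC Rm_HV 2. For keratinocytes and fibroblasts there were 81 without FB Rm_HV 2, 40 without KC Rm_HV 2, 10 without FB Rm_AD 1, and 1 without KC Rm_AD 1, KC Rm_AD 2 or KC Rm_HV 1.

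In GENCODE release 29 some of the leading genes are neighbours in the hg38 genome and others lie apart. On chromosome 2 CMPK2 (6840570 to 6866635) overlaps RSAD2 (6865806 to 6898239). On chromosome 4 CXCL9, CXCL10 and CXCL11 start at 76001275, 76021117 and 76033682. CXCL8 (ENSG00000169429.10) is on chromosome 4 at 73740506 to 73743716 and CXCL10 on the same chromosome at 76021117 to 76023497. ISG15 is on chromosome 1 at 1001138 to 1014540, MX1 on chromosome 21 at 41420304 to 41459214, TNF on chromosome 6 at 31575567 to 31578336, TNFSF15 on chromosome 9 at 114784635 to 114806126 and SIGLEC1 on chromosome 20 at 3686970 to 3707128.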

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

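Of the tests in this part, the share of RN7SL copies, the RN7SL share as a covariate, fibroblasts without the 3 libraries of lowest RN7SL share, the uniformly stronger response to Rm_HV and the other splits of the 18 contrasts were chosen only after the result was seen. The 6 genes named next stood out because the difference between Rm_HV and Rm_AD itself differed between cell types.

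CXCL8 had a difference of -2.09 ± 0.28 in log2 between fibroblasts (-1.45) and dendritic cells (0.65), adjusted p = 0.00413. JAG1, a Notch ligand, had -0.53 ± 0.09 between fibroblasts (-0.21) and dendritic cells (0.32), adjusted p = 0.0368, a call lost without any of DC Rm_AD 1 (-0.49), DC Rm_AD 2 (-0.55), DC Rm_AD 3 (-0.56), DC Rm_HV 1 (-0.52), DC Rm_HV 3 (-0.53), FB Rm_AD 2 (-0.53), FB Rm_AD 3 (-0.48), FB Rm_HV 1 (-0.52) or FB Rm_HV 3 (-0.47). INHBA had -0.65 ± 0.09 between keratinocytes (-0.28) and dendritic cells (0.38), adjusted p = 0.00444. ESPL1, the separase of dividing cells, had 1.03 ± 0.16 between keratinocytes (0.25) and dendritic cells (-0.78), adjusted p = 0.0264, lost without DC Rm_AD 1 (1.04), DC Rm_AD 3 (0.99), DC Rm_HV 3 (0.91), KC Rm_AD 2 (1), KC Rm_AD 3 (1.05) or KC Rm_HV 1 (1). OAS3 had 0.64 ± 0.11 between keratinocytes (0.15) and dendritic cells (-0.49), adjusted p = 0.031, lost without DC Rm_AD 2 (0.61), DC Rm_AD 3 (0.57), DC Rm_HV 1 or 3 (0.62 each), KC Rm_AD 1 (0.63), KC Rm_AD 2 (0.68), KC Rm_AD 3 (0.6) or KC Rm_HV 1 (0.6). SEMA3C, a secreted guidance factor, had -0.41 ± 0.07 between keratinocytes (-0.23) and dendritic cells (0.19), adjusted p = 0.0442. That call was lost with all 45 libraries in 1 fit (-0.42) and without any keratinocyte or dendritic cell library but KC Rm_HV 2 (from -0.38 to -0.44).

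Relabelling Rm_HV and Rm_AD within cell types in 80 draws, the real one included, gave as many genes as the real 4 between keratinocytes and dendritic cells in 2 of 80 draws (highest other 12), a share under 0.05. Between fibroblasts and dendritic cells 4 of 80 draws reached the real 2 genes (highest other 103), a share not under 0.05. Between keratinocytes and fibroblasts 80 of 80 draws reached the real 0, as any draw must. The highest gave 328, which points to a structure of the samples, whose nature was not tested.

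The 10 splits of 6 libraries into 3 and 3 are too few for a share under 0.05. The real count was matched by 1 of 10 splits, itself, in keratinocytes with Rm_HV (14, highest other 2), Rm_AD (132, 2), SA_AD (477, 0), CoNS_HV (830, 0) and SA_AD against CoNS_HV (193, 0). The same held in fibroblasts with SA_AD (222, 12) and against CoNS_HV (357, 0), and in dendritic cells with Rm_HV (4914, 0), Rm_AD (4508, 1), SA_AD (9455, 0), CoNS_HV (8502, 0), Rm_HV against Rm_AD (26, 1) and SA_AD against CoNS_HV (1544, 0). Where the real count was 0, 10 of 10 splits matched it: keratinocytes Rm_HV against Rm_AD (highest other 0), and fibroblasts with Rm_HV (1), Rm_AD (1), CoNS_HV (0) and Rm_HV against Rm_AD (0).

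Lower non-coding genes of keratinocytes with staphylococci were weighed first, since 160 of the 231 lower non-coding genes are pseudogenes outside the ribosomal protein families. Reads shared with RN7SL copies would make at least 50% of them such copies, and 5.6% (13 of 231) were. A library-wide yield of small RNA predicts that libraries low in RN7SL within their group are low in the other genes too. The correlation over 15 libraries was 0.59 (exact permutation p = 0.022), which is consistent with such a yield, but its slope gives -0.15 and -0.19 of drops of -0.9 and -0.86 in log2, and with that share as a covariate the medians of the lower genes went from -0.95 to -0.77 with SA_AD (45 of 175 still called, median SE 0.2 to 0.23) and from -0.87 to -0.68 with CoNS_HV (5 of 192, 0.2 to 0.25). For the 42 pseudogenes with a named parent, a lower level of the 31 parent genes is not borne out, with a parent median of -0.02 for pseudogenes at -0.9. How much of the drop the yield accounts for cannot be told from these values. The genes were picked as lower in the same contrasts, which enlarges the drop, and the slope rests on 15 libraries. No other biological explanation was tested.

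The interferon genes of fibroblasts with SA_AD could in principle be reads carried over from dendritic cell libraries. They would need 243 times the share of dendritic cell reads allowed by myeloid markers at 100 CPM or more there (median 8.63% against 0.036%). That is over the 10 times set in advance. Carried-over reads would bring every gene at the same share, so each marker sets an upper limit. The lowest need was 0.713% (RSAD2), while LYZ allowed 0.00171% and PTPRC 0.00237%. Of these markers only CD74 (2.7%) and HLA-DRA (1.4%) allowed more than 0.713%. The values argue against carry-over as the source of these interferon genes. Without the 3 fibroblast libraries of low RN7SL share 27 of 30 interferon genes were called higher, a test that rests on 1 SA_AD library assumed to vary like the other groups. A response of the fibroblasts to this group of S. aureus is left as a hypothesis, and whether species, source or single isolates matter was not tested.

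Higher TNF genes and a few lower interferon genes (2 of 30, list adjusted p = 0.065, not passed) with Rm_HV than with Rm_AD in dendritic cells might come from a uniformly stronger response to Rm_HV. In that case the interferon genes raised by R. mucosa would also be higher with Rm_HV. Their median was -0.15 in log2, with 6 of 7 lower, while 19 of 19 NF-kB targets were higher (median 0.23). These are genes of the pattern itself, so the values speak against a uniform difference in strength but are no independent test, and whether source or isolates matter stays open.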

How the results depend on the processing

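Of 345 values of the 21 counts under other settings, 192 stayed within 1.5 times, 72 were larger and 81 smaller. The balance of higher against lower calls turned in 41 of them, as in DC SA_AD vs CoNS_HV from 997 and 547 to 238 and 342 with log2(FPKM + 0.1) and in DC Rm_HV vs Rm_AD from 19 and 7 to 135 and 153 without the low-count filter. With log2(FPKM + 0.1) the median log2 of all genes moved from 0.003 to -0.04 in DC SA_AD vs CoNS_HV. In DC SA_AD vs diluent it moved from 0 to -0.225, so the turns there go with a shift of all genes. The FPKM values were used without TMM factors. In the main fit these ran from 1.078 to 1.09 in DC diluent libraries and from 0.898 to 0.901 in DC SA_AD libraries. Of 8715 values of 790 named gene results, 7908 kept their call, 807 lost it and 0 changed direction. These values cover left-out libraries (4776 of them), DESeq2, RLE factors, no low-count filter, the 2 groups alone, the replicate block and all 45 libraries. The FPKM scales, protein-coding genes only and the RN7SL covariate are not among them. All 790 had passed in the main fit, so a kept direction is little support. Of the 79 list calls a preset correlation kept 79, fry 79 and the replicate block 74. They called 94, 87 and 21 further lists. Calls lost with the block included collagens and matrix in KC Rm_AD (list adjusted p = 0.072) and NF-kB targets in KC SA_AD vs CoNS_HV (0.057). In KC CoNS_HV the block lost interferon-stimulated genes (0.052) and inflammatory cytokines (0.083). RLE factors moved no count by over 1.5 times. For all settings the cause was not tested. At this depth and n = 3, 1.5-fold changes were found for 65, 68 and 67 of 100 simulated genes, and depth was not varied. The simulated changes were in genes with a mean of at least 1 CPM and in independent libraries. They do not cover rarer genes or structure shared between libraries.

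DESeq2 gave, in keratinocytes (KC), 36 for Rm_HV, 298 for Rm_AD, 9 for Rm_HV vs Rm_AD and 293 for SA_AD vs CoNS_HV, in fibroblasts (FB) 3 for Rm_HV, 1 for Rm_AD, 1 for CoNS_HV and 15 for Rm_HV vs Rm_AD, in dendritic cells (DC) 98 for Rm_HV vs Rm_AD, and for the differences KC-FB 98, KC-DC 86 and FB-DC 64. With the 2 groups alone, FB Rm_HV gave 1, FB Rm_AD 2, FB CoNS_HV 1, DC Rm_HV vs Rm_AD 73 and DC SA_AD vs CoNS_HV 927. All 45 libraries in 1 fit gave KC-FB 1, KC-DC 14 and FB-DC 13.

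Without the low-count filter KC gave 216 for Rm_HV, 840 for Rm_AD, 768 for SA_AD, 1472 for CoNS_HV, 627 for Rm_HV vs Rm_AD and 583 for SA_AD vs CoNS_HV. FB gave 263, 265, 608, 262, 690 and 909 in the same order, DC Rm_HV vs Rm_AD 288, and the differences KC-FB 316, KC-DC 317 and FB-DC 299. Most of these genes had also been tested in the main fit. Those the filter had removed ran from 7 (DC Rm_HV vs Rm_AD) to 46 (KC CoNS_HV). The replicate block gave KC 50 for Rm_HV, 989 for Rm_AD, 1818 for CoNS_HV, 618 for Rm_HV vs Rm_AD and 661 for SA_AD vs CoNS_HV, FB 48, 111, 445, 108, 662 and 1061 in the order above, DC Rm_HV vs Rm_AD 60, and KC-FB 161, KC-DC 64 and FB-DC 84. In 0 of 18 contrasts did every pair of same-numbered libraries correlate above 0.1 (-0.06 to 0.15), the bar set for pairing. Not every library was closest to its own number, but 32 of 45 were, where 15 would be by chance, a hint from the data that the numbers share something the labels do not state.

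With log2(FPKM + 0.1), KC gave 9 for Rm_HV, 15 for Rm_AD, 303 for SA_AD, 316 for CoNS_HV and 89 for SA_AD vs CoNS_HV, FB 1 for CoNS_HV and 167 for SA_AD vs CoNS_HV, and DC 3253 for Rm_HV, 2882 for Rm_AD, 6 for Rm_HV vs Rm_AD and 580 for SA_AD vs CoNS_HV. With log2(FPKM + 1), KC gave 9, 17, 304, 310 and 90, FB 1 and 167, and DC 2975 for Rm_AD, 8 for Rm_HV vs Rm_AD and 640 for SA_AD vs CoNS_HV. With all genes above 0, KC gave 13 for Rm_AD, 247 for SA_AD, 90 for CoNS_HV, 3 for Rm_HV vs Rm_AD and 83 for SA_AD vs CoNS_HV, FB 1 for Rm_HV, 7 for Rm_AD, 129 for SA_AD, 6 for CoNS_HV, 6 for Rm_HV vs Rm_AD and 132 for SA_AD vs CoNS_HV, and DC 3107 for Rm_HV, 2650 for Rm_AD, 13 for Rm_HV vs Rm_AD and 321 for SA_AD vs CoNS_HV.

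Chosen after seeing the data, the RN7SL covariate gave KC 232 for SA_AD and 33 for CoNS_HV, and FB 111 for SA_AD and 120 for SA_AD vs CoNS_HV. Protein-coding genes only gave KC 281 for SA_AD, and fibroblasts without the 3 libraries of lowest RN7SL share, with 1 SA_AD library left and assumed to vary like the other groups, gave 87 for SA_AD and 134 for SA_AD vs CoNS_HV.

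Leaving out each library in turn gave KC Rm_HV 7 to 15, Rm_AD 18 to 357, SA_AD 295 to 405, CoNS_HV 115 to 1173, Rm_HV vs Rm_AD 0 to 1 and SA_AD vs CoNS_HV 117 to 221. FB gave 0 to 0 for Rm_HV, 0 to 1 for Rm_AD, 146 to 222 for SA_AD, 0 to 0 for CoNS_HV, 0 to 1 for Rm_HV vs Rm_AD and 174 to 302 for SA_AD vs CoNS_HV. DC gave 4160 to 4402 for Rm_HV, 3742 to 4022 for Rm_AD, 8806 to 9121 for SA_AD, 7847 to 8123 for CoNS_HV, 7 to 37 for Rm_HV vs Rm_AD and 817 to 2171 for SA_AD vs CoNS_HV. The differences gave KC-FB 0 to 81, KC-DC 1 to 30 and FB-DC 1 to 70.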

Other observations

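No test in this part was chosen after the result was seen. More genes of the dendritic cell comparisons with diluent follow. With SA_AD LAMP3 rose 88-fold, CD274 rose 7.38-fold, TNFSF13B, a survival factor of B cells, rose 11.9-fold and MYD88 rose 3.36-fold (n = 3 per group). CD74, the invariant chain of antigen presentation, rose 1.8-fold. HMOX1 rose 2.89-fold and the metal-binding MT2A rose 4.24-fold, and COL4A1, a basement membrane collagen, was 4.04-fold lower. With Rm_HV the mannose receptor MRC1 was 1.81-fold lower, the endotoxin receptor TLR4 1.51-fold lower and the inflammasome sensor NLRP3 3.43-fold lower, while CLEC4E, a receptor of mycobacterial glycolipids, rose 93.9-fold.

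Lists without a call in dendritic cells included type 2 and itch mediators (4 of 7 higher with Rm_HV, list adjusted p = 0.066), cholinergic signalling (1 higher and 1 lower of 7, list adjusted p = 0.81), mitochondrial transcripts (1 of 15 higher, list adjusted p = 0.83), collagens and matrix (3 higher and 1 lower of 11, list adjusted p = 0.3) and proteases (11 higher and 3 lower of 17, list adjusted p = 0.084). IL4R, the receptor of the type 2 cytokine interleukin 4, rose 2.02-fold with SA_AD and 1.74-fold with CoNS_HV.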
